A study of Mus musculus with 12 samples.

How the data were processed

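Total RNA from 12 mouse cell samples was amplified with a TotalPrep kit, labelled with biotin and read on Illumina bead arrays, per the labels. Samples were grouped by their labels into 4 groups of 3 replicates. The authors deposited the mean bead signal of 45281 probes per array as linear intensity, neither background-subtracted nor normalized between arrays. Beside each signal the deposited file gives a detection p-value, which steps in units of 1 in 936 and so reflects the rank of a probe among negative control spots. The authors also deposited a processed table of 20513 probes, whose values, taken here as log2, were quantile normalized. Each column correlated best with the signal of its own array. The log base is not stated and was judged from the values, since the columns rose with the log2 signal at slopes of 0.864 to 0.958 and reached 15.3, near the highest log2 signals (14.9 to 15.7). That table holds exactly the probes with a detection p-value under 0.01 on at least 1 array. The scanner software and the authors' background method are not given in the sources used here.

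Signals were processed with limma 3.58.1 in R 4.3.3. The neqc function inferred the background from the detection p-values, added an offset of 16 and quantile normalized the arrays. Probes with a detection p-value under 0.01 on at least 3 of the 12 arrays were tested, which left 18185. Of these, 15676 probes carried a gene symbol, for 10043 genes. No genome coordinates were used. A linear model with 4 group means was fitted to all 12 arrays, with moderated statistics from eBayes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Differences are the first group named minus the second, on the log2 scale, and their errors are standard errors (SE); group levels are means of log2 intensity with their SD. On arrays, the number of replicates limits the precision. A gene not detected on any of the 3 arrays of a group was treated as not above background there, and its change is given as a lower bound against the lowest detected level ("at least N-fold"). Where only some arrays of a group detected a gene, the fitted change is given with the number of arrays that did.

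A set of 27 gene lists was tested with camera in all 6 comparisons at a preset correlation between genes of 0.01, which made 162 tests adjusted together, and again with an estimated correlation and with fry. A list gene was read from its probe with the highest mean. Members past the threshold whose probe was not above background in either group compared were not counted as higher or lower, a rule set after the values were seen, but stayed in the list tests. Nanog came first in each comparison, followed by Pou5f1, Sox2, Klf4 and Myc. Further named genes were the 6 largest changes in each direction among probes past the threshold whose groups did not overlap, and at most 4 members of each list, those with the largest changes past the threshold. Dppa3 and Etv5 in comparisons with NS, and Col1a1 in hNanog iPS minus ES, fall outside this rule and were chosen after their values were seen. Lists, named-gene rule, tests and most alternatives were chosen before the data were examined; a block for array brightness, and fits to the brighter or the dimmer arrays alone, were added after the data were seen.

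Each array was projected on the line from the NS mean (0) to the ES mean (1) over all tested probes, and the iPS groups were compared by an exact two-sided permutation test. The shared difference of both iPS groups from ES was compared with 20 simulations of unchanged groups set against the same number of control arrays, and was computed again with the 3 ES arrays divided 1 and 2 in 6 ways, which was added after the data were seen. Alternatives covered the background correction, the normalization between arrays, the filter on dim probes, the authors' processed values, variants of the test, replicate number as a block, and leaving out each array in turn. The slide of each array is not given in the sources used here, so a fit with slide as a block was not run. The test was checked on simulated data, in which 96% of probes shifted by 1 log2 unit were found and 19 of 17985 unchanged probes were called; at a shift of 0.5, 28% were found.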

Results

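Gene expression was measured in mouse induced pluripotent stem (iPS) cells made with the mouse form of Nanog (mNanog iPS) or with its human ortholog (hNanog iPS), in embryonic stem (ES) cells, and in neural stem (NS) cells that lack Nanog, with 3 samples per group. Nanog is a homeodomain transcription factor of pluripotent cells. All samples carry the strain label E14Tg2A, a mouse ES cell line. The iPS and ES cells were grown in a serum-free medium with LIF, CHIR99021 at 3 µM (a GSK3 inhibitor) and PD0325901 at 1 µM (a MEK inhibitor); the growth of the NS cells is not given in the sources used here. The mean signal per array ranged from 317.5 to 561.9, and 13654 to 16776 probes were detected per array (30.2% to 37%). The labels do not say whether replicates are separate cultures, separate clones or the same RNA, so p-values measure only the spread between these samples. The form of Nanog and the clone of the iPS cells therefore cannot be told apart. Replicates of a group correlated at 0.988 to 0.996 across probes, which are not independent replicates. The arrays fell into 6 brighter ones (mean signal 470 to 562) and 6 dimmer ones (317 to 332), and each group holds both kinds. After group means were removed, arrays of the same kind from different groups correlated at a median of 0.3 (26 pairs) and arrays of different kinds at -0.254 (28 pairs). Each count of changed probes is therefore also given with brightness as a block and within each kind. In the latter fits mNanog iPS and ES have 1 brighter array each, and hNanog iPS and NS 1 dimmer array each; the spread comes from the groups with 2 arrays, and a lone array is assumed to vary like them.

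Nanog was read by a pair of probes that ranked the groups differently. At ILMN_1245732, log2 intensities were 12.22, 12.17 and 12.54 in mNanog iPS, 7.22, 7.14 and 6.87 in hNanog iPS, 11.65, 11.68 and 11.51 in ES, and 4.33, 4.49 and 4.42 in NS. At ILMN_2706623, they were 11.21, 11.49 and 11.67 in mNanog iPS, 11.07, 11.04 and 10.98 in hNanog iPS, 13.15, 13.13 and 12.83 in ES, and 4.79, 4.55 and 4.81 in NS. Neither probe was above background in NS, and the positions of the probes in the transcript are not analysed here. A probe may therefore read the introduced mouse Nanog and may fail to read human Nanog. The NS cells lack Nanog, and whether the iPS cells hold an intact endogenous gene is not given here. No signal is therefore assigned to an endogenous gene. Pou5f1, a transcription factor required for pluripotency, was at 13.23 ± 0.098, 13.31 ± 0.13 and 12.96 ± 0.2 (SD, n = 3) in mNanog iPS, hNanog iPS and ES, and was not above background in NS (4.44). Sox2, a factor of both ES and neural stem cells, lay at 9.49, 9.37, 9.87 and 9.72 in mNanog iPS, hNanog iPS, ES and NS. Klf4 lay at 10.51, 10.92, 11.03 and 5.86, and Myc at 5.01, 4.83, 4.82 and 6.64, in the same order; Myc was detected on 1, 0, 0 and 3 arrays.

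**Figure D1:**
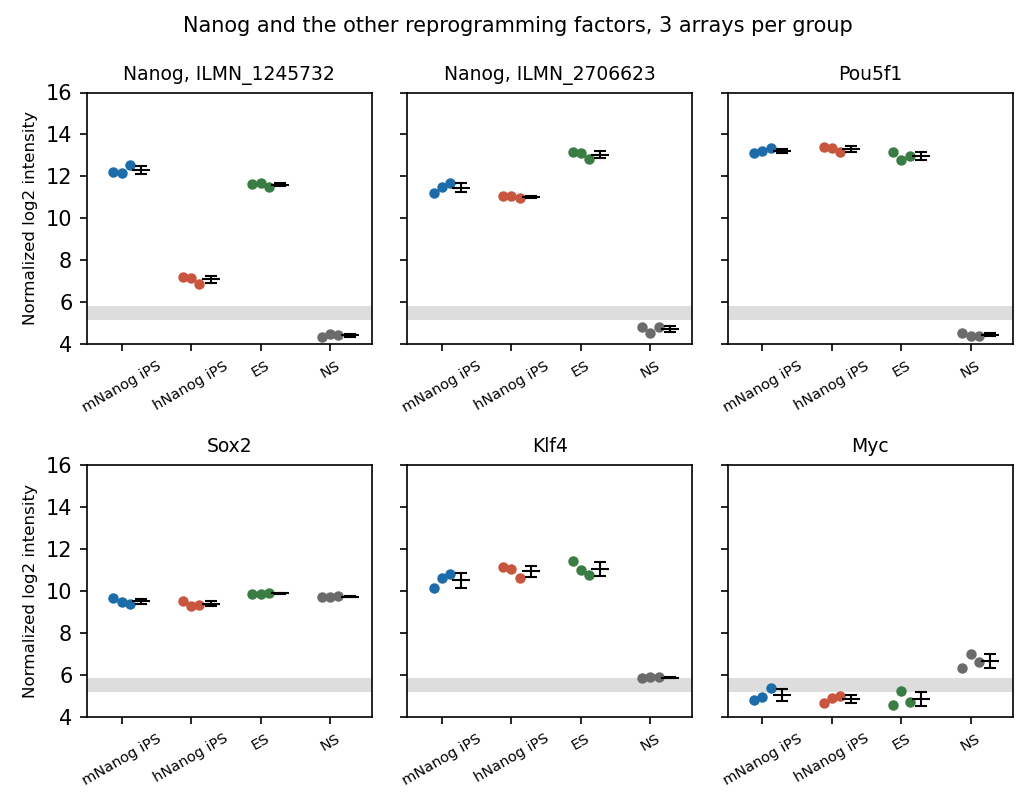
Normalized log2 intensity (vertical axis) of both Nanog probes, Pou5f1, Sox2, Klf4 and Myc in the 4 groups (horizontal axis); points are single arrays, black marks the mean ± SD of 3, and the grey band spans the lowest log2 value of a detected probe over the 12 arrays. At ILMN_1245732 the hNanog iPS mean (7.08) lies between NS (4.41) and ES (11.61), whereas at ILMN_2706623 both iPS groups (11.46 and 11.03) lie below ES (13.04).

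What separates the mNanog iPS cells from the NS cells was a broad exchange of pluripotency genes for neural stem genes. Dppa5a, an RNA-binding protein of pluripotent cells, was at least 923-fold higher in mNanog iPS at probe ILMN_3018711 (15.07 ± 0.066 against 4.5 ± 0.12; SD, n = 3), and Tfcp2l1, a transcription factor downstream of LIF, at least 333-fold higher. Olig1, a transcription factor of the oligodendrocyte lineage, was at least 686-fold lower, and Slc1a3, a glutamate transporter of glia and neural progenitors, at least 394-fold lower. Egr1, an immediate early gene induced by ERK signalling, was at least 435-fold lower. Nanog was at least 136-fold and 75.1-fold higher at its probes, and Pou5f1 at least 256-fold higher (adjusted p = 1.1e-14). Klf4 rose by 4.64 (SE 0.2), Myc changed by -1.63 (SE 0.21, adjusted p = 1.4e-05), and Sox2 by -0.22 (SE 0.094, adjusted p = 0.047). The Sox2 call was lost when any array but mNanog iPS replicate 1 or hNanog iPS replicate 1 was left out (adjusted p = 0.052 to 0.17). Among the largest changes, Laptm5, a lysosomal membrane protein, Rps4l, a ribosomal protein paralog, and Dnmt3l, a cofactor of de novo DNA methylation, were at least 333-fold, 160-fold and 137-fold higher. Ednrb, an endothelin receptor, Mt3, a brain metallothionein, and Tril, a modulator of Toll-like receptor signalling, were at least 219-fold, 176-fold and 117-fold lower.

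In mNanog iPS against NS, 17 of 18 measured core pluripotency genes rose (median 5.8, or 5.14 with genes at their bound; adjusted p = 2.5e-08), Fbxo15 at least 154-fold. Of 16 naive pluripotency genes, 15 rose (median 5.3, or 5.21 bounded; adjusted p = 2.5e-08), among them Klf2 (7.61, detected on 1 of 3 NS arrays), Esrrb (7.46) and Zfp42 (at least 118-fold); Dppa3 was at 4.64 against 4.48 (adjusted p = 0.19). Neural stem genes fell in 18 of 19 cases (median -4.13, or -3.07 bounded; adjusted p = 4.2e-08), with Bcan and Ptprz1, a proteoglycan and a receptor phosphatase of neural tissue, at least 94.2-fold and 61.2-fold lower. Of the 19, 8 were detected in NS alone (Bcan and Ptprz1 among them), as were 2 of the 12 ERK targets below, so they passed the detection filter through the group in which they are high; this holds for all 3 comparisons with NS. Of 12 ERK targets, 11 fell (median -2.21, or -2.11 bounded; adjusted p = 9e-04), including Fos (-4.92), Dusp6 (-4.83) and Spry4 (at least 5.97-fold), while Etv5 rose. These 4 lists kept their calls with an estimated correlation (adjusted p = 0.0059, 0.0059, 0.0059 and 0.036). The iPS and ES cells were grown with LIF, a GSK3 inhibitor and a MEK inhibitor, and the growth of the NS cells is not given. For ERK, Wnt and LIF targets, medium and cell type therefore cannot be told apart in any of the 3 comparisons with NS. Trophectoderm genes rose in 5 of 6 cases (adjusted p = 0.0068), with Tfap2c at least 26-fold and Tfap2a at least 9.05-fold higher; adjusted p = 0.072 with an estimated correlation. Epithelial genes rose in 6 of 8 (adjusted p = 0.0012), with the desmosomal cadherin Dsg2, the tight junction protein Cldn4 and E-cadherin (Cdh1) at least 74.8-fold, 65.1-fold and 28.5-fold higher; adjusted p = 0.072 with an estimated correlation. All 11 cholesterol synthesis genes fell (median -1.48, adjusted p = 0.0014), Dhcr7 by a log2 change of -3.05 and Cyp51 of -1.6; adjusted p = 0.25 with an estimated correlation. LIF and STAT3 targets rose in 10 of 14 and fell in 4 (adjusted p = 0.019), with Klf5 at 5.96 and Icam1 at least 23.9-fold higher; adjusted p = 0.26 with an estimated correlation. Genes of the DNA methylation machinery rose in 7 of 8 (adjusted p = 0.032), including Dnmt3b (4.78) and Tet1 (2.92); adjusted p = 0.14 with an estimated correlation. Stress response genes rose in 8 of 11 (adjusted p = 0.025), with the amino acid response genes Asns (3.5) and Chac1 (3.26, detected on 2 NS arrays) and Trib3, at least 14.1-fold; adjusted p = 0.23 with an estimated correlation. The other 17 lists did not pass. Among lineage lists these were primed epiblast (6 higher and 5 lower of 12), neuronal (2 and 8 of 10, adjusted p = 0.082), astrocyte and oligodendrocyte (0 and 6 of 9), fibroblast (5 and 3 of 8), mesenchymal (5 and 5 of 11), primitive endoderm (1 and 7 of 10), mesoderm (2 and 0 of 2), 2-cell-like (1 and 0 of 3) and germline genes (4 and 1 of 5). The rest were imprinted genes (6 and 5 of 11), Wnt targets (4 and 3 of 8), p53 targets (8 and 3 of 11), proliferation (4 and 3 of 10), glycolysis (7 and 5 of 15, or 6 lower adjusted over the list alone), interferon and antigen presentation (1 and 4 of 6), housekeeping (4 and 2 of 8) and sex-linked genes (2 and 0 of 2). Nodal was at least 60.8-fold higher, Sp5, a Wnt target, was 6.45 higher (detected on 2 NS arrays), and the imprinted genes Phlda2 and Mest went opposite ways (at least 15.5-fold higher and -3.9). Counts adjusted over the list alone were the same for every other list.

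For mNanog iPS minus NS, 13606 of 18185 probes changed, 7079 higher and 6527 lower, of which 6876 by at least 2-fold; in 75.7% of probes the groups did not overlap, against 10% by chance. The count was 14176 with brightness as a block, 13225 in the brighter and 11495 in the dimmer arrays. With median scaling it was 9128, of which 2769 were higher and 6359 lower. Leaving out NS replicate 1, 2 or 3 ended the call of the DNA methylation list (adjusted p = 0.0538, 0.0532 and 0.0568), leaving out NS replicate 3 that of LIF targets (0.052) and leaving out NS replicate 2 that of stress genes (0.075).

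Cells made with human Nanog differed from NS cells in much the same terms, with pluripotency genes higher and neural stem genes lower. Dppa5a was at least 801-fold higher in hNanog iPS (14.87 ± 0.2 against 4.5 ± 0.12; SD, n = 3), and Tfcp2l1 at least 337-fold. Olig1 was at least 737-fold lower, and Ptn, a heparin-binding growth factor of neural tissue, at least 482-fold lower. Zscan4c, a gene expressed at the 2-cell stage and in rare ES cells, was at least 7.71-fold higher. Nanog was at least 3.61-fold higher at ILMN_1245732 and at least 55.8-fold higher at ILMN_2706623, and Pou5f1 at least 272-fold. Klf4 rose by 5.06 (SE 0.2), Sox2 changed by -0.35 (SE 0.094, adjusted p = 0.0047) and Myc was at least 2.18-fold lower. Laptm5, Ifitm1, an interferon-induced membrane protein of pluripotent cells, and Rps4l were at least 290-fold, 138-fold and 137-fold higher. Egr1, Slc1a3, Ednrb and Sox9, a transcription factor of neural stem cells and glia, were at least 468-fold, 423-fold, 236-fold and 184-fold lower.

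In hNanog iPS against NS, core pluripotency genes rose in 17 of 18 cases (median 5.87, or 5.2 with genes at their bound; adjusted p = 4.2e-08), with Sall4 at least 104-fold higher, and naive genes in 15 of 16 (median 5.29, adjusted p = 5.3e-08), with Klf2 (on 1 NS array) at 7.52 and Esrrb at 7.44. Neural stem genes fell in 18 of 19 (median -4.07, or -3.97 bounded; adjusted p = 2.5e-08), Bcan at least 101-fold, and ERK targets in 11 of 12 (median -2.58, or -2.37 bounded; adjusted p = 0.00034), among them Fos (-5.81) and Dusp6 (-5.16). The 4 lists held with an estimated correlation (adjusted p = 0.0059, 0.0065, 0.0059 and 0.03). Trophectoderm genes rose in 5 of 6 (adjusted p = 0.014), Tfap2c and Tead4 at least 9.83-fold and 9.78-fold; adjusted p = 0.092 with an estimated correlation. Epithelial genes rose in 7 of 8 (adjusted p = 0.001), Dsg2 and Cldn4 at least 69-fold and 62.7-fold; adjusted p = 0.071 with an estimated correlation. Cholesterol synthesis genes fell in 9 of 11 (median -0.97, adjusted p = 0.0068), among them Mvk (-2.05, detected on 2 hNanog iPS arrays), Dhcr7 (-2.03) and Sc5d (-1.95); adjusted p = 0.28 with an estimated correlation. LIF and STAT3 targets rose in 10 of 14 and fell in 4 (adjusted p = 0.029), with Klf5 at 5.52; adjusted p = 0.28 with an estimated correlation. The 2-cell-like list had 3 of 3 genes higher (adjusted p = 0.058), Tcstv1 and Tcstv3 at least 2.47-fold and 2.05-fold. Other lists below the threshold included DNA methylation genes (6 higher and 2 lower of 8, adjusted p = 0.082), stress response genes (7 and 0 of 11, adjusted p = 0.065), primed epiblast (7 and 5 of 12), neuronal (2 and 8 of 10, adjusted p = 0.065), astrocyte and oligodendrocyte (2 and 7 of 9), fibroblast (0 and 5 of 8), primitive endoderm (1 and 6 of 10), mesoderm (2 and 0 of 2), imprinted (5 and 5 of 11) and Wnt targets (4 and 3 of 8). The counts adjusted over the list alone were the same for every list given here.

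For hNanog iPS minus NS, 13695 probes changed, 7380 higher and 6315 lower, 6938 of them by at least 2-fold; groups did not overlap in 77.9% of probes, against 10% by chance. The count was 14348 with brightness as a block, 14161 in the brighter and 10815 in the dimmer arrays. With median scaling it was 8870, of which 3785 were higher and 5085 lower, and the call of Sox2 ended. The call of LIF targets ended in the dimmer arrays, 1 per group here (adjusted p = 0.052), and leaving out NS replicate 1, 2 or 3 ended it too (adjusted p = 0.0567, 0.0527 and 0.0676).

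The reference comparison, ES against NS cells, separated pluripotency genes from neural stem genes as the iPS comparisons did. Dppa5a was at least 924-fold higher in ES (15.08 ± 0.07 against 4.5 ± 0.12; SD, n = 3), and Ifitm1 at least 314-fold. Nanog was at least 83.9-fold higher at ILMN_1245732 and at least 225-fold higher at ILMN_2706623. Dppa3, a maternal factor that also marks naive pluripotent cells, lay at 8.57 ± 0.12 in ES and was not above background in the other 3 groups. Ptn, Ednrb and Ccnd2, a D-type cyclin, were at least 458-fold, 224-fold and 208-fold lower. Pou5f1, Tfcp2l1 and Rps4l were at least 214-fold, 302-fold and 183-fold higher, and Klf4 rose by 5.17 (SE 0.2, adjusted p = 1.5e-10). Sox2 differed by 0.15 (SE 0.094, adjusted p = 0.17), a difference that turned negative with median scaling and with cyclic loess. Myc was at least 2.07-fold lower, Egr1 changed by -8.86 (SE 0.11), Slc1a3 by -8.86 (SE 0.15) and Olig1 by -9.98 (SE 0.37). Each of these 3 genes was detected on 1 of 3 ES arrays, so the sizes of these changes rest mostly on ES signals at background.

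In ES against NS, core pluripotency genes rose in 17 of 18 cases (median 5.27, or 4.45 with genes at their bound; adjusted p = 2.5e-08), Fbxo15 at least 187-fold, and all 16 naive genes rose (median 5.65, or 5.57 bounded; adjusted p = 1.4e-08), with Klf2 (on 1 NS array) at 7.45 and Esrrb at 7.44. Neural stem genes fell in 18 of 19 (median -3.71, or -3.22 bounded; adjusted p = 3.4e-08), with Sox9 and Bcan at least 175-fold and 96.1-fold lower, and ERK targets in 11 of 12 (median -3.11, or -2.82 bounded; adjusted p = 0.00022), Fos at least 82.3-fold. With an estimated correlation these lists had adjusted p = 0.0059, 0.0059, 0.0059 and 0.027. Trophectoderm genes rose in 5 of 6 (adjusted p = 0.0066), Tfap2c at least 67.7-fold and Cdx2 at least 5.95-fold; adjusted p = 0.071 with an estimated correlation. Cdx2 was detected in ES alone and passed the detection filter through that group. Epithelial genes rose in 7 of 8 (adjusted p = 0.00053), with adjusted p = 0.066 at an estimated correlation. All 11 cholesterol synthesis genes fell (median -1.49, adjusted p = 8e-04); adjusted p = 0.23 with an estimated correlation. LIF and STAT3 targets rose in 10 of 14 and fell in 3 (adjusted p = 0.01); adjusted p = 0.23 with an estimated correlation. Neuronal genes fell in 8 of 10 (median -2.37, or -1.33 bounded; adjusted p = 0.023), among them Map2 (-6.11) and Gad1 (-2.67, detected on 1 ES array), while Stmn2 was at least 44-fold higher; adjusted p = 0.11 with an estimated correlation. Of the 10 neuronal genes, 6 were detected in NS alone, so they passed the detection filter through the group in which they are high. DNA methylation genes (6 higher and 1 lower of 8, adjusted p = 0.078) and stress response genes (7 and 1 of 11, adjusted p = 0.13) did not pass. Neither did primed epiblast (8 and 4 of 12), astrocyte and oligodendrocyte (2 and 6 of 9), fibroblast (0 and 5 of 8), primitive endoderm (1 and 7 of 10), mesoderm (1 and 0 of 2), 2-cell-like (0 and 0 of 3), imprinted (5 and 5 of 11) and Wnt lists (5 and 3 of 8). Counts adjusted over the list alone were again the same.

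For ES minus NS, 13671 probes changed, 7382 higher and 6289 lower, 6933 of them by at least 2-fold; groups did not overlap in 76.2% of probes, against 10% by chance. The count was 14226 with brightness as a block, 13308 in the brighter, 11569 in the dimmer arrays and 8788 with median scaling, of which 2856 were higher and 5932 lower. Without NS replicate 1, 2 or 3, neuronal genes seen only on the 3 NS arrays left the test and the list no longer passed (adjusted p = 0.52, 0.531 and 0.484), nor did it with cyclic loess (0.057).

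On the line from NS (0) to ES (1), mNanog iPS arrays lay at 0.9275 ± 0.0059 and hNanog iPS arrays at 0.9419 ± 0.005 (SD, n = 3). Single ES and NS arrays, placed with themselves left out, lay at 0.9917 ± 0.012 and 0.007243 ± 0.017. The iPS groups differed by 0.0144 (exact two-sided permutation p = 0.1, the smallest this design allows). The difference was 0.00406 with median scaling (p = 0.9), 0.0283 with cyclic loess (p = 0.2) and 0.00883 with the authors' processed values (p = 0.1), and p was 0.3 without ES replicate 1 and 0.2 without hNanog iPS replicate 3. All 3 pluripotent groups shared 2418 probes at least 2-fold higher and 2961 at least 2-fold lower than NS. Of the 6933 probes that differed at least 2-fold between ES and NS, 733 (10.6%) also differed at least 2-fold between mNanog iPS and ES, 532 towards the NS level and 201 away from it. In hNanog iPS the numbers were 516 (7.44%), 377 and 139. The same ES arrays choose and score these probes, which favours the NS direction; with the 3 ES arrays divided 1 and 2 between the steps in 6 ways, 70% to 72.8% lay towards NS in mNanog iPS and 71.3% to 74% in hNanog iPS. In 20 simulations of unchanged iPS groups no probe was counted, so they give no balance of directions to set beside these shares. Probes at background in ES can differ from it only upward, which is towards NS where NS is higher. The division does not remove this, so the shares are in part set by the floor. Dppa3 and Krt42, a type I keratin, are examples at which both iPS groups stayed at the background level of NS. These counts fell to 156 and 101 with the authors' processed values, read as log2.

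Cells made with mouse Nanog differed from ES cells in the fibroblast and mesenchymal lists, which were higher in the iPS cells, and in Dppa3, Krt42 and Otx2, which were lower. Serpinf1, a secreted serpin of mesenchymal cells, was at least 20.3-fold higher (9.93 ± 0.15 against 4.45 ± 0.082; SD, n = 3), and P2rx7, an ATP-gated channel, at least 33.4-fold. Krt42 was at least 14.3-fold lower and Dppa3 at least 7.75-fold lower. Otx2, a transcription factor of the epiblast, changed by -2.88 (SE 0.16, adjusted p = 7.1e-08); it was detected on 1 of 3 mNanog iPS arrays, so the size rests mostly on signals at background. Nanog was called in opposite directions by its probes, 0.69 (SE 0.12, adjusted p = 0.00085) at ILMN_1245732 and -1.58 (SE 0.13, adjusted p = 1.9e-06) at ILMN_2706623; median scaling ended the first of these calls and kept the second. Sox2 changed by -0.37 (SE 0.094, adjusted p = 0.009), and Pou5f1 (0.26, adjusted p = 0.097), Klf4 (-0.53, adjusted p = 0.066) and Myc (0.19, adjusted p = 0.53) did not pass. Pou5f1 passed without ES replicate 1 (adjusted p = 0.031), and Klf4 without mNanog iPS replicate 3 or ES replicate 3 (adjusted p = 0.036 in both). Fndc3a and Trim50 were at least 13-fold and 11.6-fold higher, Xlr4a, an X-linked lymphocyte-regulated gene, was 4.48 higher (SE 0.084), and the channel gene Pkd2l1 4.38 higher (SE 0.11). Klk8, a serine protease, was at least 5.75-fold lower, Lrrc15 changed by -3.45, Grb7, an adaptor protein detected on 2 mNanog iPS arrays, by -3.05, and Igfbp2, which binds insulin-like growth factors, by -2.99.

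In mNanog iPS against ES, fibroblast genes rose in 6 of 8 cases (6 adjusted over the list alone; median 2, or 1.36 with genes at their bound; adjusted p = 2.2e-06), with decorin (Dcn) and Col1a1, which codes for a fibrillar collagen, at least 7.64-fold and 5.87-fold higher and Mmp2 and Thy1 at least 3-fold and 2.5-fold. Col1a1 and Dcn were detected in mNanog iPS alone among the 4 groups, so they passed the detection filter through that group. Mesenchymal genes rose in 7 of 11 (8 adjusted over the list alone; median 0.5, or 0.45 bounded; adjusted p = 0.001), among them Cd44 (at least 2.91-fold), Tgfbr2 (2.18) and Itga5 (at least 2.54-fold). With an estimated correlation, adjusted p = 0.035 for the fibroblast and 0.036 for the mesenchymal list. The other lists did not pass. Core pluripotency genes were higher in 3 and lower in 4 of 18, with Dnmt3l 2.99 higher, and naive genes were higher in 1 and lower in 6 of 16 (7 adjusted over the list alone). Of 12 primed epiblast genes, 3 were higher and 6 lower, including Lefty2 (-2.12) and Lefty1 (-1.71), which code for Nodal antagonists. Neural stem genes were higher in 3 and lower in 3 of 19 (median -0.04, mean 0.12, test direction up), with Sox9 at least 2.2-fold higher. Nefm, a neurofilament gene detected on 1 ES array, was 4.16 higher and the only neuronal gene of 10 past the threshold. Astrocyte and oligodendrocyte genes were higher in 2 and lower in 3 of 9, with Mbp, a myelin protein, at least 2.94-fold lower. Trophectoderm genes were higher in 2 and lower in 4 of 6, with Cdx2, detected in ES alone, at least 4.53-fold lower and Tfap2c changed by -1.38. Primitive endoderm genes were higher in 5 and lower in 1 of 10, with Col4a1 and Col4a2, basement membrane collagens, at least 5.01-fold and 2.49-fold higher. The mesoderm list had 1 of 2 higher and 1 lower (Gsc, -1.76), and the 2-cell-like list 1 of 3 higher, Zscan4c at least 1.17-fold. Imprinted genes were higher in 4 and lower in 5 of 11 (6 adjusted over the list alone; median -0.26, mean 0.29, test direction up); Dlk1 was at least 2.91-fold higher, Igf2 1.75 higher and Phlda2 changed by -1.11. Dlk1 was detected in mNanog iPS alone and passed the detection filter through that group. Both measured sex-linked genes were lower, Eif2s3y (-0.76, adjusted p = 0.0026) and Uty (-0.53, adjusted p = 0.044, detected on 2 mNanog iPS arrays). ERK targets were higher in 4 and lower in 1 of 12, with Etv4 2.91 and Phlda1 (on 1 ES array) 2.22 higher. Wnt targets were higher in 1 and lower in 2 of 8, and LIF targets higher in 4 and lower in 2 of 14 (3 adjusted over the list alone; median 0.06, mean -0.05, test direction up). Hprt, a purine salvage enzyme, was at least 7.98-fold higher, at 8.59 ± 0.068 against 4.86 ± 0.15 in ES, and was detected on 3 mNanog iPS arrays, on 0 ES arrays and on 3 NS arrays (5.82). E14Tg2A is known as an Hprt-deficient line.

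For mNanog iPS minus ES, 5968 probes changed, 2899 higher and 3069 lower, and of the 1135 changed at least 2-fold, 747 were higher and 388 lower; groups did not overlap in 44.3% of probes, against 10% by chance. The count was 7179 with brightness as a block, 3849 in the brighter and 3800 in the dimmer arrays. With median scaling 927 probes changed, 605 higher and 322 lower, and the calls of Sox2 and of Nanog at ILMN_1245732 ended, while the fibroblast and mesenchymal lists kept theirs.

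Cells made with human Nanog differed from ES cells in 3 genes of the 2-cell stage, which were higher, and in the signals of both Nanog probes, Dppa3 and Krt42, which were lower. Zscan4c was at least 5.99-fold higher (8.17 ± 0.038 against 4.6 ± 0.049; SD, n = 3), and P2rx7 at least 21.3-fold. Nanog changed by -4.54 (SE 0.12, adjusted p = 2.4e-10) at ILMN_1245732 and by -2.01 (SE 0.13, adjusted p = 4.3e-07) at ILMN_2706623. Lrrc15, Krt42 and Dppa3 were at least 23.3-fold, 15.4-fold and 8.33-fold lower. Pou5f1 rose by 0.35 (SE 0.11, adjusted p = 0.039), a call lost without mNanog iPS replicate 2 (0.055), hNanog iPS replicate 1 (0.14) or 2 (0.11), or ES replicate 2 (0.16) or 3 (0.095). Sox2 changed by -0.5 (SE 0.094, adjusted p = 0.0019), while Klf4 (-0.11, adjusted p = 0.75) and Myc (0.01, adjusted p = 0.97, not above background in either group) did not pass. Klf4 was positive without hNanog iPS replicate 3 (0.049) or ES replicate 1 (0.074), and Myc negative without hNanog iPS replicate 2 (-0.011) or 3 (-0.063) or ES replicate 1 (-0.111) or 3 (-0.052). Lmo2, a LIM-only factor of blood development, was at least 6.15-fold higher, Pkd2l1 3.45 higher, Grhl2, an epithelial transcription factor, 3.13 higher and the myosin chaperone gene Unc45b (on 1 ES array) 3.13 higher. Slit2, an axon guidance ligand, and 4933402E13Rik were at least 14.3-fold and 6.8-fold lower.

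In hNanog iPS against ES, all 3 measured 2-cell-like genes rose (median 2.05, or 0.94 with genes at their bound; adjusted p = 2.9e-05), with Tcstv1 and Tcstv3 at least 1.92-fold and 1.59-fold higher; adjusted p = 0.019 with an estimated correlation. Of 13 genes written for this list 3 were measured, and Tcstv1 and Tcstv3 passed the detection filter through hNanog iPS alone, so the list test depends on the outcome it measures. Naive pluripotency genes fell in 8 of 16 cases and rose in 1 (9 lower adjusted over the list alone; median -0.32, adjusted p = 0.0039), among them Spic (-1.18), whereas Gbx2 was 0.88 higher; adjusted p = 0.071 with an estimated correlation. Dppa3 and Nanog were also among the lower members. Dppa3 was detected in ES alone and passed the detection filter through that group, and Nanog is the introduced gene. The mean level of the list was 10.49 to 10.525 on hNanog iPS arrays, 10.61 to 10.638 on mNanog iPS arrays and 11.062 to 11.112 on ES arrays. Cholesterol synthesis genes rose in 10 of 11 (median 0.47, adjusted p = 0.00034), with Lss 0.78 higher; adjusted p = 0.22 with an estimated correlation. The sex-linked genes Eif2s3y (-1.94) and Uty (-0.88, detected on 2 hNanog iPS arrays), both on the Y chromosome, fell (adjusted p = 0.029); adjusted p = 0.22 with an estimated correlation. The call was lost in the dimmer arrays, with 1 of hNanog iPS (adjusted p = 0.056), and with cyclic loess (0.05, just over the threshold). The other lists did not pass. Core pluripotency genes were higher in 3 (4 adjusted over the list alone) and lower in 5 of 18, with Dnmt3l 1.46 and Dppa2 1.23 higher. Primed epiblast genes were higher in 1 (2 adjusted over the list alone) and lower in 5 of 12, including Otx2 (-1.95) and Lefty2 (-1.62), and neural stem genes lower in 2 of 19 (1 adjusted over the list alone), with Vim, an intermediate filament gene, at -1.57. Neuronal genes were higher in 1 of 10 (median -0.04, mean 0.27, test direction up), Nefm (on 1 ES array) by 2.13, and astrocyte and oligodendrocyte genes lower in 2 of 9, Mobp (on 2 hNanog iPS arrays) by a log2 change of -2.22. Fibroblast genes were higher in 1 and lower in 1 of 8, and Col1a1 was at 4.48 ± 0.078 against 4.54 ± 0.12. Trophectoderm genes were higher in 2 and lower in 3 of 6, with Cdx2, detected in ES alone, at least 4.87-fold lower, Tfap2c at -2.78 and Tfap2a at -2.21. Primitive endoderm genes were higher in 2 and lower in 1 of 10, Dab2 at least 2.14-fold higher, and mesoderm genes higher in 1 and lower in 1 of 2, Gsc by a log2 change of -2.29. Imprinted genes were higher in 3 and lower in 3 of 11 (4 adjusted over the list alone), Mest (on 2 hNanog iPS arrays) at -1.62. ERK targets were higher in 3 (4 adjusted over the list alone) and lower in 2 of 12, Etv4 by 1.92; Wnt targets were higher in 2 and lower in 2 of 8 (3 lower adjusted over the list alone), Notum at -1.52; and LIF targets were higher in 1 and lower in 5 of 14. Interferon and antigen presentation genes were higher in 2, H2-D1 (2.06) and B2m (1.69), and lower in 1 of 6.

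For hNanog iPS minus ES, 4752 probes changed, 2500 higher and 2252 lower, and of the 796 changed at least 2-fold, 486 were higher and 310 lower; groups did not overlap in 41.9% of probes, against 10% by chance. The count was 5397 with brightness as a block, 3320 in the brighter and 1402 in the dimmer arrays. With median scaling 730 probes changed, 555 higher and 175 lower, and the calls of Pou5f1, Sox2, Spic, Lss and Uty ended; without any hNanog iPS replicate, Tcstv1 and Tcstv3 fell out of the detection filter and the 2-cell-like list was not tested.

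The iPS groups differed from ES cells in similar directions. P2rx7 and Pkd2l1 were higher in both, and Dppa3, Krt42, Lrrc15 and Cdx2 lower in both. Dppa3 and Cdx2 were detected in ES alone, so they passed the detection filter through that group. Across probes, the differences from ES correlated at 0.716 (Spearman 0.71), where 20 simulations of groups without any change against shared controls gave a mean of 0.5004 (0.4859 to 0.5172). The covariance was 0.1885 against a simulated 0.01139. Both groups were higher at 1748 probes (398.5 by chance) and lower at 1598 (380.1 by chance), and 96 probes were called in opposite directions. The same 3 ES arrays enter both comparisons, which alone gives the simulated correlation. Divided 1 and 2 between the comparisons in 6 ways, so that no ES array was shared, they gave covariances of 0.1551 to 0.1836. Most of the covariance therefore does not come from the sharing of arrays, though a trait common to all 3 ES samples would still enter both. The divided correlations were 0.537 to 0.668. The simulated 0.5004 holds for shared arrays and is no reference for them.

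**Figure D2:**
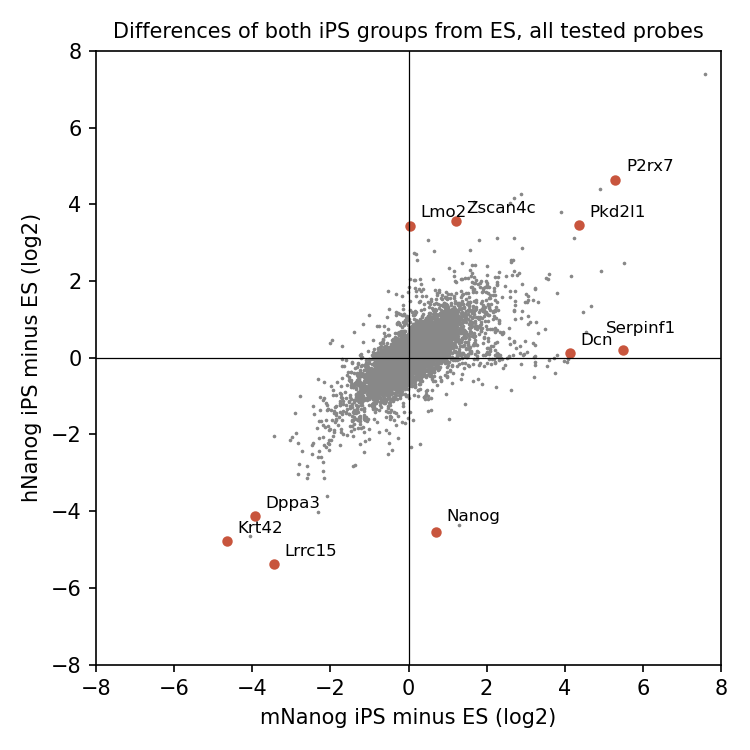
Fitted log2 difference from ES of mNanog iPS (horizontal axis) and hNanog iPS (vertical axis) for all 18185 tested probes (grey), with named genes in red. Genes not above background in ES have only bounds, which are at least 33.4-fold and 21.3-fold for P2rx7 (high in both), 20.3-fold for Serpinf1 in mNanog iPS and 5.99-fold for Zscan4c in hNanog iPS, and the Nanog probe ILMN_1245732 lies at 0.69 and -4.54.

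The direct comparison of the iPS groups showed a lower signal of Nanog probe ILMN_1245732 in the cells made with human Nanog. Their fibroblast and mesenchymal lists were lower, and 3 genes of the 2-cell stage were higher. Clone and form of Nanog cannot be told apart here. Nanog changed by -5.23 (SE 0.12, adjusted p = 1.1e-10) at ILMN_1245732 and by -0.43 (SE 0.13, adjusted p = 0.05, at the threshold) at ILMN_2706623. It is not known here which of these probes reads the introduced mouse or human Nanog. The second call was lost when any array but mNanog iPS replicate 1, ES replicate 3 or NS replicate 2 was left out (adjusted p = 0.052 to 0.15). Serpinf1 was at least 21.4-fold lower (4.66 ± 0.13 against 9.93 ± 0.15; SD, n = 3), and Timp3 and Timp2, inhibitors of metalloproteinases, at least 9.66-fold and 8.69-fold lower. Lmo2 was at least 6.03-fold higher and Zscan4c, detected on 2 of 3 mNanog iPS arrays, 2.35 higher (SE 0.11, adjusted p = 2.9e-08). Pou5f1 (0.09, adjusted p = 0.69), Sox2 (-0.13, adjusted p = 0.45, positive with median scaling), Klf4 (0.42, adjusted p = 0.22) and Myc (-0.18, adjusted p = 0.65) did not pass. S100a6, a calcium-binding protein, and Lox, which crosslinks collagen, were at least 14.1-fold and 7.61-fold lower. Eras, a Ras family gene of ES cells, was 2.43 higher, Gpc3, a glypican, 2.4 higher, Ephb1, an ephrin receptor, 2.35 higher and Gm5662 at least 3.6-fold higher; Eras and Ephb1 were each detected on 1 mNanog iPS array. Hprt was at least 8.41-fold lower, detected on 3 arrays of mNanog iPS and on 0 of hNanog iPS, although E14Tg2A is known as Hprt-deficient.

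**Figure D3:**
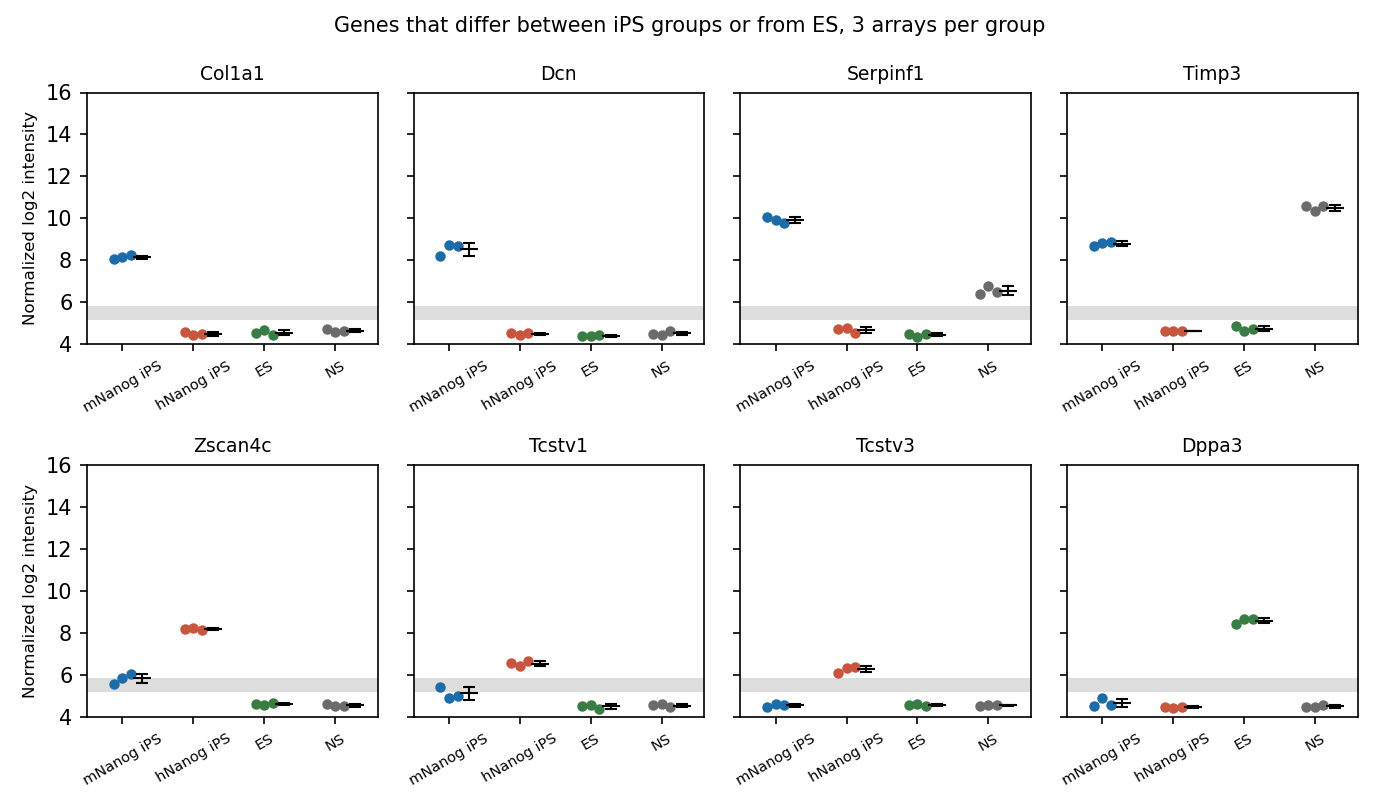
Normalized log2 intensity (vertical axis) of genes that differ between the iPS groups or from ES, in the 4 groups (horizontal axis); points are single arrays, black marks the mean ± SD of 3, and the grey band spans the lowest log2 value of a detected probe over the 12 arrays. Col1a1 and Dcn reach 8.14 and 8.52 in mNanog iPS alone, Zscan4c is highest in hNanog iPS (8.17), and Dppa3 is above background in ES alone (8.57).

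In hNanog iPS against mNanog iPS, fibroblast genes fell in 6 of 8 cases (median -1.86, or -1.79 with genes at their bound; adjusted p = 5e-10), Dcn and Col1a1 at least 8.04-fold and 6.18-fold and Acta2, a smooth muscle actin, at least 2.72-fold; adjusted p = 0.0099 with an estimated correlation. Acta2 passed at probe ILMN_2693895 alone. Its probes ILMN_2710353, ILMN_2710354 and ILMN_2923445 changed by -0.22, -0.54 and -0.33 (adjusted p = 0.39, 0.058 and 0.15), with signals at or near background in both groups. Mesenchymal genes fell in 5 of 11 (5 lower and 1 higher adjusted over the list alone; median -0.48, adjusted p = 0.00077), with Cd44 at least 3.06-fold lower and Vim at -1.55; adjusted p = 0.035 with an estimated correlation. All 3 measured 2-cell-like genes rose (median 1.73, or 0.91 with genes at their bound; adjusted p = 3.7e-06), with Tcstv3 and Tcstv1 at least 1.56-fold and 1.88-fold higher; adjusted p = 0.012 with an estimated correlation. Both passed the detection filter through hNanog iPS alone. ERK targets fell in 4 of 12 (5 adjusted over the list alone; median -0.27, or -0.12 bounded; adjusted p = 0.0068), among them Phlda1 (-1.52) and Etv4 (-0.99); adjusted p = 0.071 with an estimated correlation. Proliferation genes rose in 3 of 10 (median 0.23, adjusted p = 0.016), Cdc20 by 0.67; adjusted p = 0.092 with an estimated correlation. Cholesterol synthesis genes rose in 5 of 11 (7 adjusted over the list alone; median 0.51, adjusted p = 0.0068), Dhcr7 by 1.02 and Fdps by 0.53; adjusted p = 0.28 with an estimated correlation. The other lists did not pass. Core pluripotency genes were lower in 2 of 18 (1 adjusted over the list alone), with Dnmt3l at -1.54, and naive genes lower in 4 of 16 (5 adjusted over the list alone), with Klf5 at -0.45. Primed epiblast genes were higher in 4 of 12 (4 higher and 2 lower adjusted over the list alone), Otx2 (on 1 mNanog iPS array) by 0.93, and neural stem genes lower in 4 of 19, Sox9 at least 2.32-fold. Nefm, at -2.03, was the only neuronal gene of 10 past the threshold; of 9 astrocyte and oligodendrocyte genes 1 was higher (2 adjusted over the list alone) and 1 lower, Gja1 at -1.02. Trophectoderm genes were higher in 1 (2 adjusted over the list alone) and lower in 2 of 6, Tfap2a at -1.72 and Tfap2c at -1.4, and primitive endoderm genes higher in 1 and lower in 2 of 10, Col4a1 (on 2 hNanog iPS arrays) at -2.53. Mesoderm genes were higher in 1 and lower in 1 of 2 (median 0.03, test direction down). Imprinted genes were higher in 2 and lower in 5 of 11, with Dlk1 at least 3.06-fold lower, Mest (on 2 hNanog iPS arrays) at -1.25 and Phlda2 0.92 higher. Dlk1 passed the detection filter through mNanog iPS alone. Wnt targets were higher in 0 (1 adjusted over the list alone) and lower in 1 of 8 (median 0.11, mean -0.06, test direction down), Notum at -1.04, and LIF targets higher in 1 and lower in 3 of 14 (5 lower adjusted over the list alone), Socs3 at -0.72.

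For hNanog iPS minus mNanog iPS, 2495 probes changed, 1168 higher and 1327 lower, and of the 449 changed at least 2-fold, 129 were higher and 320 lower; groups did not overlap in 33.1% of probes, against 10% by chance. The count was 3055 with brightness as a block, 1767 in the brighter and 533 in the dimmer arrays, and the fibroblast median was -1.92, -1.89 and -2.1 in these. Of the 533, 178 were higher and 355 lower, and of 2148 with cyclic loess, 768 were higher and 1380 lower. With array weights it was 4246, of which 2274 were higher and 1972 lower, so the larger direction depends on the setting. In the dimmer arrays, where hNanog iPS has 1 array, the cholesterol call was lost (adjusted p = 0.052); whether brightness or the smaller number of arrays ended it is open. With median scaling 311 probes changed and the calls of Phlda1, Etv4, Cdc20, Fdps, Klf5, Otx2, Gja1, Mest, Notum, Socs3, Tfap2c and the second Nanog probe ended; without any hNanog iPS replicate the 2-cell-like list, left with Zscan4c, was not tested.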

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

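The tests of expression retained from neural stem cells and of array brightness were chosen after the results were seen. A second fibroblast list and a second 2-cell list were written for patterns already seen, but before the values of their own genes were. The splits of the arrays were chosen before. The results below stand here because the iPS groups, made with the mouse or the human form of Nanog, differed from each other by the limma test. They comprise 2495 probes and 6 gene lists. The median change (hNanog iPS minus mNanog iPS) was -1.86 for fibroblast (-1.79 with genes at their bound), 1.73 for 2-cell-like (0.91), -0.27 for ERK target (-0.12), 0.23 for proliferation, -0.48 for mesenchymal and 0.51 for cholesterol synthesis genes. In the same order, the medians were -0.66, 0.46, -0.06, 0.2, -0.19 and 0.34 with the authors' processed values. With median scaling they were -1.58, 1.7, -0.19, 0.54, -0.25 and 0.73, so the sizes depend on the processing. Of single genes, Lmo2 and Gm5662 were at least 6.03-fold and 3.6-fold higher in hNanog iPS, and log2 changes were 2.43 for Eras, 2.4 for Gpc3, 2.35 for Zscan4c, 2.35 for Ephb1 and -5.23 for Nanog at ILMN_1245732. In mNanog iPS, Eras and Ephb1 were detected on 1 array and Zscan4c on 2. Serpinf1, S100a6, Timp3, Timp2 and Lox were at least 21.4-fold, 14.1-fold, 9.66-fold, 8.69-fold and 7.61-fold lower. Groups of 3 arrays are too small for a test of single arrays.

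The 6 arrays of each comparison allow 10 splits, too few for a share under 0.05. For mNanog iPS minus NS, the real split gave 13346 probes and the highest other split 0, and 2 of the 10 splits gave as many lists, 10 in the real split and 12 in the highest other. In each of the remaining tests 1 split, the real one, reached the real value. For hNanog iPS minus NS these were 13766 probes (highest other 0) and 9 lists (8); for ES minus NS, 13453 (0) and 10 (8). For mNanog iPS minus ES they were 5240 (0) and 2 (1); for hNanog iPS minus ES, 4484 (97) and 4 (1); for hNanog iPS minus mNanog iPS, 2091 (108) and 7 (1). A split follows the brighter and dimmer arrays in 4 comparisons, and gave 97 probes for hNanog iPS minus ES, 108 for hNanog iPS minus mNanog iPS, and 0 for mNanog iPS minus NS and for ES minus NS.

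Fibroblast genes were higher in mNanog iPS than in hNanog iPS. With brightness as a block, 6 of 6 members that changed and were above background kept their calls. Col1a1 and Dcn passed the detection filter through mNanog iPS alone, so their calls are given no weight here. Brightness as the whole cause is argued against for Thy1, Acta2, Fbln2 and Mmp2 only. Of these, Acta2 changed at ILMN_2693895 and not at its other probes. Of the 6, 4 (Col1a1, Thy1, Dcn and Mmp2) were higher than in NS. For Thy1 (6.91 in mNanog iPS, 5.99 in NS) and Mmp2 (7.17 and 6.49), expression retained unchanged from neural stem cells is argued against. Both were picked for being high on these mNanog iPS arrays, and retained expression that rose further stays open. Col1a1 and Dcn passed the detection filter through mNanog iPS alone, so their test against NS is given no weight. Any retention stays open for the other 2 (Acta2 and Fbln2). The argument takes the NS samples as the source of the iPS cells, and the line of the NS samples is open (below). RNA from fibroblast-like cells in the mNanog iPS cultures may contribute and stays open: 0 of 12 measured members of a second fibroblast list of 30 genes were higher in mNanog iPS than in both other groups (6% of all genes were; Fisher's exact p = 1), but that list had been written without genes already seen as higher. Hprt, which an Hprt-deficient line such as E14Tg2A should lack, was high in the same group (8.59, against 4.85 in hNanog iPS and 4.86 in ES). It was also detected on 3 of 3 NS arrays (5.82) with the same line label, so the signal is not confined to mNanog iPS. The Y-linked Eif2s3y was detected on all iPS and ES arrays and on 0 of 3 NS arrays, while Uty, also Y-linked, was detected on 2 of them, so whether the NS samples are of the same line is open too. Other cells or another line in the mNanog iPS cultures stay open beside the form of Nanog, which was not tested, and the comparison of mouse with human Nanog carries that doubt. A difference between clones cannot be told apart from the form of Nanog either.

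Genes of the 2-cell stage were higher in hNanog iPS than in mNanog iPS and ES. With brightness as a block, 3 of 3 members kept their calls. Tcstv1 and Tcstv3 were detected on all 3 hNanog iPS arrays, which are of both kinds, and in no other group. They passed the detection filter that way, so their calls are given no weight here. Brightness as the whole cause is argued against for Zscan4c only, which was also detected on 2 mNanog iPS arrays. A 2-cell-like state in part of the hNanog iPS cells is a hypothesis that stays open. Of 4 measured members of a second list (20 written), 2 were higher than in both groups, Pramel31 (6.55 in hNanog iPS) and Pramel16 (6.33), but neither was above background in the other groups, so each passed the detection filter only by being high in hNanog iPS and the count decides nothing. Bulk RNA does not show how many cells carry these transcripts.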

How the results depend on the processing

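The brightness block, the fits to brighter or dimmer arrays, the division of the ES arrays and their values were chosen after the data were seen. Of 15826 values of named genes under alternatives, 15328 kept direction and call, 461 lost a call, 23 gained one and 14 reversed. Except where stated, the causes were not tested. Median scaling gave 8870 probes for hNanog iPS minus NS, 8788 for ES minus NS, 927 for mNanog iPS minus ES, 730 for hNanog iPS minus ES and 311 for hNanog iPS minus mNanog iPS. It moved the median of all probes to -0.325, -0.0449, -0.238, -0.0645, 0.166 and 0.255 (main values 0.0756, 0.118, 0.113, -0.0327, -0.00395 and 0.027), in the order mNanog iPS, hNanog iPS and ES minus NS, the iPS groups minus ES, and hNanog iPS minus mNanog iPS. With 1 probe per gene, fewer tests gave 7840, 7891, 7852, 3800 and 3114 in the first 5 of these. The fits to brighter or dimmer arrays, in which both the kind and the number of arrays change, gave 3849 (brighter) and 3800 (dimmer) for mNanog iPS minus ES, and 1402 and 533 (dimmer) for hNanog iPS minus ES and minus mNanog iPS. The first count compares 1 array with 1 and the last 2 compare 1 with 2; a lone array is assumed to vary like the other groups. Array weights gave 4246 for hNanog iPS minus mNanog iPS, 2274 higher and 1972 lower (main 1168 and 1327).

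Probes of the ES to NS difference that also differed in mNanog iPS numbered 316 with normexp at offset 50, 302 without background correction and 156 with the authors' values; in hNanog iPS they numbered 198, 191 and 101, and 339 with 1 probe per gene. The shared difference from ES had r = 0.732 with normexp, 0.732 without background correction, 0.689 with median scaling, 0.699 without a filter, 0.744 with the authors' values, 0.698 to 0.742 with single arrays left out, and 0.537 to 0.668 with the ES arrays divided. Lists called were 67 with median scaling, 18 with an estimated correlation and 136 with fry, which does not compare a list with other genes; with single arrays left out they were 35 to 44 (main 39). Without any hNanog iPS replicate, the 2-cell-like list gave no value.

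Reversed were Sox2 in ES minus NS (-0.214 with median scaling, -0.081 with cyclic loess) and in hNanog iPS minus mNanog iPS (0.167 with median scaling). In hNanog iPS minus ES, Klf4 was 0.097 with median scaling, 0.023 with array weights and -0.265 to 0.074 with single arrays left out; Myc was -0.066 with cyclic loess, -0.004 with the authors' values, -0.062 with array weights and -0.111 to 0.208 with single arrays left out. None of these passed the test. Slide as a block was not run, as no slide is given. Signal over background limits genes at the level of undetected probes, for which only bounds are given.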

Other observations

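The genes below were chosen after their values were seen. In 121 probes both iPS groups and NS lay at least 2-fold above ES, and in 135 at least 2-fold below. Above ES were Nfix, a transcription factor of the neural lineage (8.31 in mNanog iPS, 6.89 in hNanog iPS, 11.05 in NS and 4.71 in ES), and Anxa5, a calcium-dependent phospholipid-binding protein (10.77, 10.67, 11.44 and 8.56). A probe with no gene name, ILMN_2476405, lay at 12.78, 12.58 and 13 in the same 3 groups and was detected on 0 of 3 ES arrays. Below ES were Tdrd12, a Tudor domain gene of the germline (7.52, 6.98 and 5.03 against 10.11 in ES), and Krt42 at 3 probes.

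Hprt lay at 8.59 ± 0.068 in mNanog iPS, 4.85 ± 0.27 in hNanog iPS, 4.86 ± 0.15 in ES and 5.82 ± 0.075 in NS (SD, n = 3), and was detected on 3, 0, 0 and 3 arrays. E14Tg2A is known as an Hprt-deficient line. Lgals1, a galectin, lay at 11.25, 9.49, 9.71 and 12.12 in the same order, and Eif2s3y, on the Y chromosome, at 9.58, 8.4, 10.34 and 4.41, detected on 3, 3, 3 and 0 arrays. Uty, also on the Y chromosome, was detected on 2, 2, 3 and 2 arrays (5.81, 5.46, 6.34 and 5.27).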
